A study of Mus musculus with 16 samples.

How the data were processed

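The series holds RNA-seq of mouse liver from 16 libraries in 4 groups of 4: WT DMSO, WT CDDO-Me, KO untreated and KO CDDO-Me. According to the labels, CDDO-Me was given at 3 mg/kg by intraperitoneal injection in DMSO, 24 h and 1 h before partial hepatectomy, DMSO alone was given at 1 µL/g, and the day 0 sample is the liver removed at the operation. The labels describe 1 µg of total RNA depleted of ribosomal RNA, directional libraries, and paired reads of 150 bases on 3 lanes of a HiSeq. They do not state for each library that it came from a separate animal, so p-values here measure the spread between samples, and they give no batch or date. Libraries are named by group and the replicate number of their title.

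The deposited count table holds whole-number read counts per gene for 33730 Ensembl gene IDs, 1 column per library and 0 columns of other samples. Per the submitters' processing notes, CASAVA 1.8.2, cutadapt 1.2.1, TopHat2 2.1.0, HTSeq 0.6.1p1, DESeq2 and the build GRCm38.p5 were used, with no role or order stated. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. The deposited FPKM table holds, per the file headers, counts per kilobase of gene length scaled to the library total, made by the authors. Checked against the counts, each FPKM equals the count divided by 1 length per gene and by the library's total, with a largest relative deviation of 1.8e-07. Counts were used for the main tests and FPKM for alternatives only.

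Gene symbols, positions and types came from GENCODE M21 (GRCm38), which matched 33629 IDs and left 101 unmatched. Symbols used by more than 1 ID numbered 26. Of all genes, 1080 had no read in any library. All libraries had the same pattern of Xist and Y-linked genes, so the planned model with sex as a covariate was not run. A check of each pair of libraries found no duplicated library, the lowest chi-square per degree of freedom being 15.1. In a principal component analysis of 2000 genes, components 1 to 3 held 30.6%, 21.8% and 12.6% of the variance.

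The tests, gene lists, naming rule and other settings were fixed before the data were examined. The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, quasi-likelihood) in R 4.3.3, with TMM scaling and filterByExpr by group, which left 16206 genes. The 16 libraries shared 1 estimate of the spread with 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The 4 pairwise contrasts are KO or treated group minus the other, and the interaction is the WT drug response minus the KO drug response. Standard errors are on the log2 scale, and CPM values are given as mean ± SD. The numbers of genes called (unadjusted p under 0.05 in parentheses) were 118 (2484) for WT CDDO-Me vs WT DMSO, 21 (2564) for KO CDDO-Me vs KO untreated, 223 (2287) for KO untreated vs WT DMSO, 534 (2769) for KO CDDO-Me vs WT CDDO-Me and 21 (1383) for the interaction.

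Gene lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 36 lists in each contrast. An estimated correlation was used beside it. Of the lists called with the preset value, 20, 16, 14, 21 and 22 in the contrasts in the order above, 1, 0, 0, 1 and 0 were called with the estimate, in both cases the NRF2 target genes. By the rotation test fry, 7, 2, 3, 15 and 4 lists moved on balance 1 way in the contrasts in the order above. The 7 in WT with the drug were NRF2 target, glutathione, heme and iron, fatty acid synthesis, Kupffer cell, bile acid and unfolded protein genes (fry adjusted p = 1.4e-05 to 0.0411). The lists, written from general knowledge, were NRF2 target genes, glutathione synthesis and transfer, pentose phosphate and NADPH supply, cytochrome P450 xenobiotic enzymes, glucuronidation and sulfation, bile acid synthesis and transport, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation and PPAR alpha targets, glucose metabolism, urea cycle and amino acid catabolism, cell cycle and proliferation, immediate early genes and regeneration priming, acute phase response, interferon response, inflammatory cytokines and chemokines, unfolded protein and ATF4 stress response, heat shock response, proteasome subunits, circadian clock, heme and iron handling, male-biased and female-biased liver genes, mitochondrially encoded genes, and nuclear-retained and unspliced-rich RNAs. Marker lists covered hepatocytes (general, pericentral and periportal), cholangiocytes, Kupffer cells and macrophages, neutrophils and monocytes, lymphocytes, stellate cells and fibroblasts, endothelial cells, erythroid cells, and adipocyte, mesothelial and pancreatic cells.

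Genes were named by a rule. Nfe2l2 was given in every library, and Nqo1, Gclc, Gclm, Txnrd1, Srxn1 and Hmox1 in each contrast, called or not. To these were added up to 6 of the largest rises and 6 of the largest falls per contrast among called genes with an official symbol and a mean log2 CPM of at least 1. Their CPM ranges had to be non-overlapping between the groups, except in the interaction. For each list with a camera call or at least 3 called members, up to 4 called members with the smallest p were taken, and for other lists up to 2 members. The text names part of what the rule selects.

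Replicate numbers were checked as a possible pairing by correlating the deviations of same-numbered libraries from their group means. All 4 pairs exceeded r = 0.1 for WT DMSO and KO untreated (0.371 to 0.483) and for no other pair of groups, where 1 to 3 of 4 did. In none of the 4 pairs was each library the other's best match. The blocked counts are given beside that contrast in the text.

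The other settings chosen in advance were DESeq2 size factors, upper-quartile scaling, DESeq2 1.42.0 (Wald test), limma-voom with quality weights, no filter on low counts, a filter of 1 CPM in 8 libraries, mitochondrial genes left out, only the groups compared, the replicate number as a block, a minimum fold of 1.5, an adjusted p under 0.01 for overlaps, limma on log2 FPKM (pseudocount 1 or 0.1, mean FPKM of at least 0.5 or no filter), the 2 libraries with description numbers 25 and 27 left out, and each library left out in turn. Those added after the data were seen were the 4 libraries richest in sense-intronic reads left out, the share of such reads as a covariate, the counts of WT CDDO-Me 1 thinned to the median total, a block in a fit of only the groups compared, and the ribosomal RNA split as a term. Scores are means over a list's genes of log2 CPM centred on all libraries.

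The tests were tried on simulated data with the depths and spread of these libraries and 100 genes changed at each of 2 sizes. At a fold of 2, edgeR recovered 27%, 38%, 45%, 30% and 13% in the contrasts in the order above, and at a fold of 4 it recovered 77%, 82%, 90%, 80% and 65%. It made 3 to 6 false calls per simulation. Of the calls DESeq2 made, 14.2% to 23.4% were false. In each contrast camera found the 1 changed list and made 0 false calls. The simulated genes varied independently and the lists were drawn at random, so this does not test camera on correlated genes. In WT CDDO-Me vs WT DMSO the estimated correlation was 0.907 for proteasome and 0.741 for interferon genes. No simulated library was made to stand apart, as the 4 richest in sense-intronic reads do. At these depths a gene with a change of 2-fold or less was thus often not detectable.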

Results

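RNA-seq of mouse liver covered 16 libraries in 4 groups of 4, from wild-type (WT) mice given the vehicle DMSO, WT mice given CDDO-Me, Nrf2-null (KO) mice left untreated and KO mice given CDDO-Me. NRF2, the product of Nfe2l2, is a transcription factor that switches on antioxidant and detoxification genes, and CDDO-Me (bardoxolone methyl) is a synthetic triterpenoid known to activate it. The drug was injected at 3 mg/kg, 24 h and 1 h before partial hepatectomy, and the tissue is the day 0 liver taken at the operation. Gene counts summed to between 12002317 and 99284626 per library, and 20453 to 27594 genes were detected. The largest total belonged to WT CDDO-Me 1. The totals were 12002317 to 26948425 in WT DMSO, 13809649 to 99284626 in WT CDDO-Me, 14019793 to 24194378 in KO untreated and 21432833 to 33827313 in KO CDDO-Me. The KO controls are labelled untreated. Taken as mice given no injection, they leave drug and vehicle inseparable in KO CDDO-Me vs KO untreated, vehicle goes with genotype in KO untreated vs WT DMSO, and the interaction of genotype and treatment holds vehicle only in its KO part.

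Nfe2l2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641, GRCm38) was read first, because it checks the genotype labels. Its levels in CPM (counts scaled to the TMM library size) were 42.8, 66.2, 55.1 and 74.9 in WT DMSO 1 to 4, and 39.5, 36.6, 45.5 and 38.001 in WT CDDO-Me 1 to 4. They were 51.7, 35.5, 19.9 and 21.3 in KO untreated 1 to 4, and 19.8, 15.7, 21.0 and 19.0 in KO CDDO-Me 1 to 4. The means ± SD (n = 4 each) were 59.8 ± 13.9, 39.9 ± 3.93, 32.1 ± 14.8 and 18.9 ± 2.25. The library labelled KO untreated 1 therefore lay inside the WT range for this gene, while its mean score over 30 NRF2 target genes was −1.39, the lowest of the 16. It was also the lowest of the 16 on the hepatocyte (−0.644) and proteasome (−0.646) lists. Its share of sense-intronic and TEC (unsettled loci) reads was the highest, 0.967% of counts, so the NRF2 score alone does not settle its label. WT DMSO 1 and 2, also rich in such reads, scored −0.173 and −0.263 on NRF2 targets. Nqo1 read 0.507 CPM in KO untreated 1 and 3.20 to 4.21 CPM in WT DMSO. In a chromosome 14 segment described below, 8 genes were lower in every KO library than in every WT library. Among them Gm27177 had 0 or 1 counts per KO library and 68 to 1125 per WT library. These values argue against a WT sample under that label. Nfe2l2 was higher in KO untreated 1 and 2, both rich in sense-intronic and TEC reads, than in KO untreated 3 and 4. The labels do not say which part of the gene was deleted, and reads outside that part would not check the label. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Nfe2l2 was lower in KO CDDO-Me than in WT CDDO-Me, with a log2 fold change of −1.08 ± 0.26 (SE, adjusted p = 0.0283). It was not called in the 8 edgeR fits that each left out 1 library of these groups (highest adjusted p = 0.102, without KO CDDO-Me 2). For KO untreated vs WT DMSO the log2 fold change was −0.90 ± 0.25 (edgeR adjusted p = 0.0969), and −1.22 (adjusted p = 0.0155) without KO untreated 1.

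In WT liver, CDDO-Me raised enzymes that handle oxidants and electrophiles. Nqo1, a quinone reductase, went from 3.80 ± 0.44 to 38.3 ± 6.39 CPM (SD, n = 4 in each group), a log2 fold change of 3.33 ± 0.30 (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.6e-05). Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, went from 263.7 ± 31.2 to 1157 ± 182 CPM (log2 fold change 2.13 ± 0.20, edgeR adjusted p = 3.24e-05), and Srxn1, sulfiredoxin, from 28.9 ± 7.28 to 193.2 ± 55.4 CPM (2.74 ± 0.27, 3.24e-05). Txnrd1, thioredoxin reductase, rose 2.23-fold (edgeR adjusted p = 0.0222). Gclm, the modifier subunit of the Gclc enzyme, had a log2 fold change of 1.06 ± 0.27 and missed the threshold (edgeR adjusted p = 0.0959), which it passed without WT DMSO 3 (adjusted p = 0.0402). So did Hmox1, heme oxygenase 1, at 0.52 ± 0.63 (edgeR adjusted p = 0.677). It read 294.4 CPM in WT DMSO 4 and 20.5 to 47.2 CPM in the other WT DMSO libraries, and without WT DMSO 4 it was called at a log2 fold change of 2.07 (edgeR adjusted p = 0.0216). Its direction turned downward without WT DMSO 1 and 2 and KO untreated 1 and 2. In all, 118 of 16206 genes were called, 90 upward and 28 downward. The balance rested on single libraries: the counts up and down were 108 and 111 without WT DMSO 4, 124 and 86 without WT DMSO 3, and 51 and 3 without WT CDDO-Me 2.

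Of 30 NRF2 target genes, 18 rose and 0 fell in WT with the drug (26 up, adjusted over the list alone), and 29 had a positive fold change. The list test camera gave an adjusted p of 9.05e-37, and the call held with an estimated correlation (adjusted p = 0.0184). Cbr3, a carbonyl reductase, had the largest rise that the naming rule ranked, 105.1-fold from 0.234 ± 0.093 to 24.6 ± 8.12 CPM (edgeR adjusted p = 1.49e-06). Of 24 glutathione genes tested, 10 rose (16 up and 1 down, adjusted over the list alone; camera adjusted p = 4.02e-18, adjusted p = 0.167 with an estimated correlation). The transferases Gstm1 went from 664.9 to 4842 CPM and Gstm3 from 39.9 to 405.8 CPM (edgeR adjusted p = 5.04e-05 and 0.000174). Gsta1 rose 18.1-fold (edgeR adjusted p = 2.6e-05), and it shares near-identical sequence with Gsta2 and Gm3776, so its level is uncertain. Of 13 pentose phosphate and NADPH genes, 3 rose (4 up and 1 down, adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.49 with an estimated correlation). They were Tkt, Pgd and G6pdx, with log2 fold changes of 1.07, 0.99 and 1.23. Of 22 glucuronidation and sulfation genes, 4 rose (7 up and 1 down, adjusted over the list alone; camera adjusted p = 0.0053, adjusted p = 0.62 with an estimated correlation). Among them were Ugdh, which makes UDP-glucuronic acid, 3.07-fold, and the transferase Ugt2b35, 4.08-fold.

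**Figure D1:**
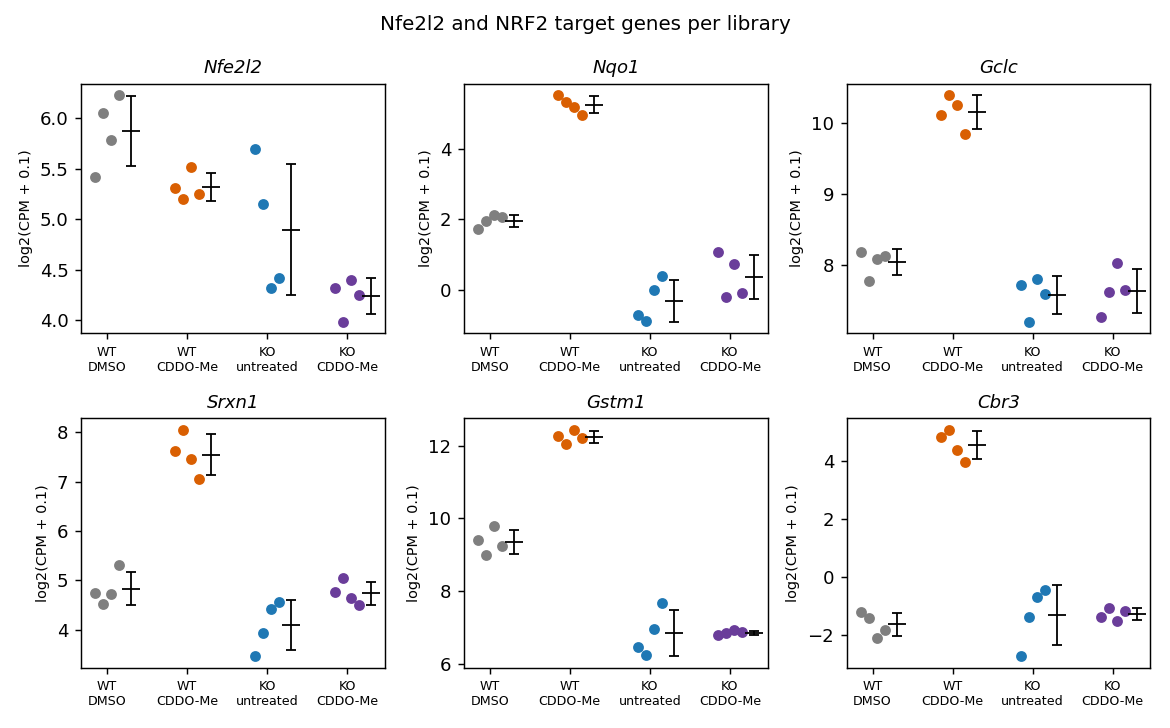
Expression of Nfe2l2 and 5 NRF2 target genes per library, as log2(CPM + 0.1) on the y axis for the 4 groups on the x axis. Each point is 1 library, and the black dash with bars is the mean ± SD of 4 libraries. Nqo1, Gclc, Srxn1, Gstm1 and Cbr3 stood highest in all WT CDDO-Me libraries, while Nfe2l2 of KO untreated 1 read 51.7 CPM.

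The efflux pumps Abcc4 and Abcc3 rose by log2 fold changes of 2.09 ± 0.25 and 1.35 ± 0.22 (edgeR adjusted p = 0.000273 and 0.00621). They were 2 of 25 bile acid genes tested (camera adjusted p = 0.0268, adjusted p = 0.49 with an estimated correlation). Of 24 heme and iron genes, 3 rose (7 up, adjusted over the list alone; camera adjusted p = 3.07e-06, adjusted p = 0.222 with an estimated correlation). These were the heme transporter Slc48a1 3.45-fold, biliverdin reductase B (Blvrb) 3.60-fold and ferritin light chain Ftl1 2.01-fold. Fgf21, a hormone secreted by liver, went from 0.807 ± 0.479 to 33.8 ± 38.1 CPM (edgeR adjusted p = 0.00129), with single WT CDDO-Me libraries between 7.89 and 90.3 CPM. Psat1, of serine synthesis, rose 16.3-fold (edgeR adjusted p = 0.00206). Cyp2a5 rose from 253.7 ± 139.7 to 3084 ± 465 CPM and Cyp2a4 20.2-fold (edgeR adjusted p = 0.00491 and 0.00204), as a pair of near-identical cytochrome P450 genes whose reads may be shared.

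Of 22 fatty acid and triglyceride synthesis genes, 3 fell and 0 rose in WT with the drug, with 20 negative fold changes (12 down, adjusted over the list alone; camera adjusted p = 1.28e-08, adjusted p = 0.146 with an estimated correlation). Fasn, fatty acid synthase, went from 1659 ± 598 to 553.6 ± 154.2 CPM (log2 fold change −1.58 ± 0.33, edgeR adjusted p = 0.0372). Acacb, an acetyl-CoA carboxylase, and Thrsp, a regulator of lipogenesis, fell by 1.54 and 2.27 on the log2 scale (edgeR adjusted p = 0.0126 and 0.0373). Of 25 urea cycle and amino acid catabolism genes, the aminotransferase Got1 and serine dehydratase Sds fell, by 1.30 and 1.61 on the log2 scale (camera adjusted p = 0.000443, adjusted p = 0.569 with an estimated correlation). Chrna4, a nicotinic acetylcholine receptor subunit, fell by 5.09 on the log2 scale, Atg16l2 by 2.09, Lacc1 by 1.93, and H2-Q6, a class I histocompatibility gene, by 1.88 (edgeR adjusted p = 0.0165, 0.00961, 0.0226 and 0.0492). H2-Q6 read 119.0 CPM in WT DMSO 4 and at most 40.03 in the other libraries of that group. Phf11c fell by 3.39 on the log2 scale (edgeR adjusted p = 0.045), with 196.1 CPM in WT DMSO 1 and 9.70 to 31.5 CPM in the other WT DMSO libraries.

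Of 16 Kupffer cell and macrophage markers, 4 rose in WT CDDO-Me vs WT DMSO (11 up and 1 down, adjusted over the list alone; camera adjusted p = 3.73e-10, adjusted p = 0.227 with an estimated correlation). They were the scavenger receptor Marco 3.65-fold, Cd5l 2.72-fold, Adgre1 1.82-fold and Clec4f 1.76-fold. Of 16 stellate cell and fibroblast markers and 16 endothelial markers, 15 of each had positive fold changes and 0 were called (camera adjusted p = 4.3e-05 and 0.000164, adjusted p = 0.49 and 0.49 with an estimated correlation). The interferon response list had 29 of 30 negative fold changes and 0 genes called by edgeR (15 down, adjusted over the list alone; camera adjusted p = 0.00104, adjusted p = 0.694 with an estimated correlation). WT DMSO 4 stood apart on that list, with a score of 2.81 against −0.586 to −0.465 in the other WT DMSO libraries. Without it the median log2 fold change of the list went from −1.27 to 0.23 with a camera adjusted p of 0.199. The other lists that passed camera in WT CDDO-Me vs WT DMSO had 1 gene called by edgeR, or 0. Those upward by limma camera were unfolded protein and ATF4 (adjusted p = 1.04e-07), fatty acid oxidation and PPAR alpha (3.95e-06), proteasome (0.0011), cholesterol synthesis (0.00122), heat shock (0.0016), pericentral hepatocyte (0.00634) and acute phase (0.0268). Glucose metabolism passed downward (limma camera adjusted p = 0.0248). None of these calls held with an estimated correlation (adjusted p = 0.346 to 0.734). The proteasome list had no settled direction: without WT DMSO 1 and 2 and KO untreated 1 and 2 it passed downward (limma camera adjusted p = 0.00951, adjusted p = 0.829 with an estimated correlation).

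Single libraries moved the count of 118 in WT CDDO-Me vs WT DMSO: it was 74, 62, 210 and 219 without WT DMSO 1, 2, 3 and 4, and 69, 54, 59 and 61 without WT CDDO-Me 1, 2, 3 and 4. Of 36 genes, a part of those that the naming rule selected as called, 18 stayed called without each library in turn. Txnrd1, Thrsp, Fasn, Acacb, Got1, Sds, Tkt, Pgd, G6pdx, Ftl1, Marco, Clec4f, Adgre1, Chrna4, Phf11c, Atg16l2, Lacc1 and H2-Q6 did not, with highest adjusted p of 0.0525 (Atg16l2, without WT CDDO-Me 2) to 0.178 (Got1, without WT CDDO-Me 2). The libraries also fell into a technical split: nuclear ribosomal RNA genes took 0.173 to 0.634% of counts in WT DMSO 1 to 3 and WT CDDO-Me 2 to 4, and 0.00108 to 0.0368% in WT DMSO 4, WT CDDO-Me 1 and all KO libraries. Without WT DMSO 4 and WT CDDO-Me 1, the WT contrast compared only libraries of the first set. The KO libraries stayed in that fit and entered its filter, scaling and shared spread. It called 104 genes, 70 of them among the 118, and 16 NRF2 target genes and 9 glutathione genes rose. The second set holds 1 library of each WT group, too few for a value of its own.

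Whether the drug acts without Nrf2 was asked in KO liver, where none of the NRF2 panel passed. Of 16206 genes 21 were called there and 118 in WT, with 2564 and 2484 at an unadjusted p under 0.05. The gap depended on the setting: 88 and 104 genes were called without WT DMSO 4 and WT CDDO-Me 1, and 133 and 219 without WT DMSO 4 alone. The log2 fold changes for KO CDDO-Me vs KO untreated were 0.75 ± 0.33 for Nqo1, 0.07 ± 0.19 for Gclc, 0.63 ± 0.27 for Gclm, 0.63 ± 0.22 for Txnrd1, 0.59 ± 0.25 for Srxn1 and 1.21 ± 0.65 for Hmox1 (edgeR adjusted p = 0.296, 0.869, 0.29, 0.24, 0.283 and 0.353). Of the 30 NRF2 target genes 0 were called by edgeR, and 20 had positive fold changes (camera adjusted p = 0.0114 upward, adjusted p = 0.767 with an estimated correlation). Of the 21 called genes, 17 were higher and 4 lower, a balance that other settings did not keep. The counts up and down were 73 and 60 without WT DMSO 4, 34 and 29 with limma on log2(FPKM + 1), 34 and 39 with the share of intronic reads as a covariate, and 1 and 3 without WT DMSO 1 and 2 and KO untreated 1 and 2. Prtn3, a neutrophil protease, went from 0.55 ± 0.27 to 13.9 ± 9.94 CPM, Isyna1, of inositol synthesis, from 5.72 ± 1.08 to 68.5 ± 43.3 CPM (edgeR adjusted p = 0.00928 and 0.003). The chemokine Cxcl1 went from 12.1 ± 3.76 to 138.5 ± 103.0 CPM, and Atf3, a stress-induced transcription factor, from 1.43 ± 0.55 to 13.8 ± 4.69 CPM (edgeR adjusted p = 0.0158 and 0.03). Dnajc12, a co-chaperone, rose 6.42-fold (edgeR adjusted p = 0.0119). Thymidine phosphorylase (Tymp) and Cyp2d22 fell by 1.12 and 0.67 on the log2 scale (edgeR adjusted p = 0.0121 and 0.0246).

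Of 27 acute phase genes, 2 rose and 26 had positive fold changes in KO CDDO-Me vs KO untreated (20 up, adjusted over the list alone; camera adjusted p = 1.63e-20, adjusted p = 0.306 with an estimated correlation). They were metallothionein Mt1, from 81.1 ± 47.8 to 477.0 ± 159.5 CPM, and the plasma protein gene Itih3, from 1235 ± 117 to 3428 ± 910 CPM (edgeR adjusted p = 0.0282 and 0.0212). Of 29 immediate early genes, Atf3 rose and 26 had positive fold changes (10 up, adjusted over the list alone; camera adjusted p = 1.16e-09, adjusted p = 0.306 with an estimated correlation). The libraries richest in intronic reads were WT DMSO 1 and 2 and KO untreated 1 and 2, at 0.673 to 0.967% of counts against 0.186 to 0.407% in the others. Without those 4, neither list had a gene called by edgeR, and without WT DMSO 4, which enters through the shared spread, they had 12 and 4. Unfolded protein and ATF4 genes and proteasome genes passed camera upward with 0 called (adjusted p = 1.72e-05 and 2.66e-07, both adjusted p = 0.767 with an estimated correlation). Cytochrome P450, endothelial and cell cycle genes passed downward with 1, 0 and 0 called (camera adjusted p = 0.00387, 0.00178 and 0.00272, adjusted p = 0.767 with an estimated correlation in each). The count of 21 was 9, 4 and 11 without KO untreated 1, 2 and 3, 12, 5 and 13 without KO CDDO-Me 1, 2 and 3, and 133 without WT DMSO 4. Isyna1 stayed called without each library in turn, whereas Prtn3, Cxcl1, Atf3, Dnajc12, Mt1, Tymp, Cyp2d22 and Itih3 did not, with highest adjusted p of 0.0563 (Prtn3, without KO untreated 2) to 0.162 (Atf3, without KO untreated 2).

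**Figure D2:**
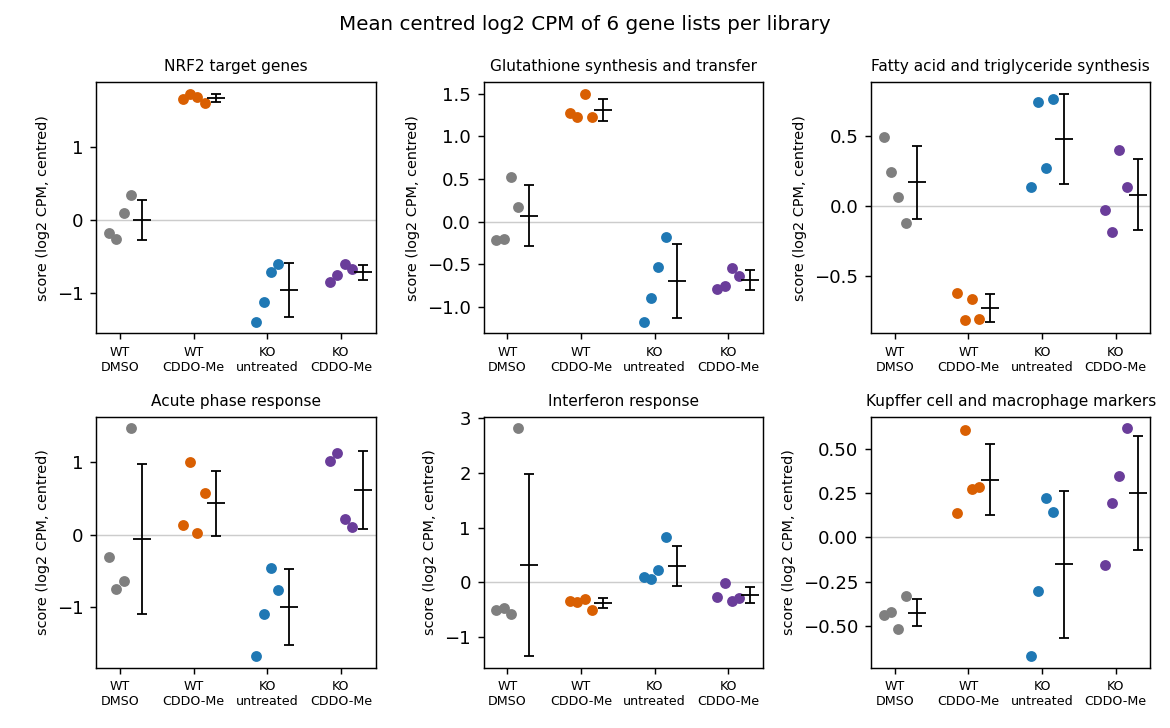
Scores of 6 gene lists per library, each the mean over the list's genes of log2 CPM centred on all 16 libraries (y axis), for the 4 groups (x axis). Points are libraries and the black dash with bars is the mean ± SD of 4. The NRF2 target score lay between 1.60 and 1.73 in WT CDDO-Me, and the interferon score of WT DMSO 4 was 2.81.

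The drug responses in the 2 genotypes were then compared. WT was measured against mice given vehicle and KO against mice labelled untreated, so each difference below holds any vehicle effect beside that of genotype. The interaction test, WT response minus KO response, called 21 genes, all with a positive difference. By edgeR 0 went the other way, with 1383 genes at an unadjusted p under 0.05 in either direction, while DESeq2 called 114 positive and 62 negative. Cbr3 and Gsta1 had log2 differences of 6.999 ± 0.67 and 5.405 ± 0.60 (edgeR adjusted p = 0.000198 and 0.000517), and Gstm3 (4.16 ± 0.53), Gsta2 (3.37 ± 0.44), Gstm1 (2.96 ± 0.39) and Gclc (2.07 ± 0.28), each at an edgeR adjusted p of 0.00241. Cyp2a4, Nqo1, Srxn1, Abcc4, Blvrb and Marco differed by 6.91, 2.58, 2.15, 2.14, 1.76 and 2.86 on the log2 scale (edgeR adjusted p from 0.0051 to 0.0183). Of 30 NRF2 target genes, 7 were called (17 adjusted over the list alone; camera adjusted p = 3e-27, adjusted p = 0.0585 with an estimated correlation), and of 24 glutathione genes 5 (camera adjusted p = 1.86e-15, adjusted p = 0.19 with an estimated correlation). Gclm, Txnrd1 and Hmox1 did not differ detectably between genotypes, with log2 differences of 0.43 ± 0.38, 0.53 ± 0.31 and −0.69 ± 0.90 (edgeR adjusted p = 0.874, 0.741 and 0.938). Acute phase genes had 26 of 27 negative differences and 0 called by edgeR (11 adjusted over the list alone; camera adjusted p = 4.42e-12, adjusted p = 0.338 with an estimated correlation), and endothelial markers 16 of 16 positive and 0 called (7 adjusted over the list alone; camera adjusted p = 2.91e-10, adjusted p = 0.19 with an estimated correlation). The count of 21 was 48 without KO untreated 1 and 32 without WT DMSO 4, and 26 without WT DMSO 4 and WT CDDO-Me 1, where 19 of the 21 were called again. Nqo1 and Srxn1 lost their calls in 4 and 2 of the edgeR fits leaving out 1 library (highest adjusted p = 0.0664 and 0.0548). For Nqo1 these were without WT CDDO-Me 1 or 2 or KO untreated 3 or 4, and for Srxn1 without KO untreated 3 or KO CDDO-Me 3.

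Of the genes called in WT, 2 were also called in KO, both upward: Dnajc12 and Pla2g7, a lipoprotein-associated phospholipase that the naming rule had not selected and that was named after its values were seen. Independent lists would share 0.0944 upward. Across 16206 genes, which are not independent replicates, the fold changes correlated at r = 0.399, with a covariance of 0.136 against 0.000125 in the mean of 20 simulations without effects. The simulated libraries are independent, whereas WT DMSO 1 and 2 and KO untreated 1 and 2 stood apart together. Without these 4, r was −0.0397 and the covariance −0.0127, so no shared drug response is read from r. These contrasts share no library. They shared 9 genes without WT DMSO 4 and 3 without WT DMSO 3 or KO untreated 4. They shared 1 without WT DMSO 1 or 2, WT CDDO-Me 3 or 4, or KO CDDO-Me 3 or 4, and 0 without KO untreated 2 or KO CDDO-Me 2.

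**Figure D3:**
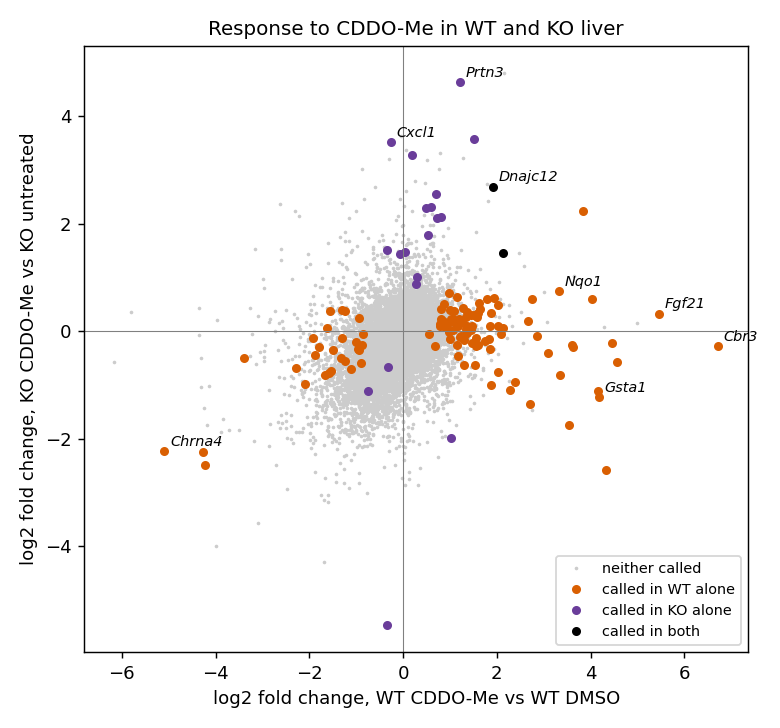
Log2 fold change of each of the 16206 tested genes with CDDO-Me in WT (x axis, against WT DMSO) and in KO (y axis, against KO untreated). Coloured points are genes called in WT, in KO or in both, and grey points are genes called in neither. Cbr3 read 6.72 in WT and Prtn3 4.63 in KO.

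The genotypes were also compared without the drug, as KO untreated vs WT DMSO. Nqo1 was 0.758 ± 0.354 CPM in KO untreated against 3.80 ± 0.44 in WT DMSO (log2 fold change −2.31 ± 0.32, edgeR adjusted p = 0.00206). Gclc, Gclm, Txnrd1, Srxn1 and Hmox1 had log2 fold changes of −0.45 ± 0.19, −0.12 ± 0.27, −0.91 ± 0.22, −0.71 ± 0.25 and −2.83 ± 0.68, none called (edgeR adjusted p = 0.293, 0.929, 0.0543, 0.19 and 0.0502). Txnrd1 was called without WT DMSO 1 or 2 (edgeR adjusted p = 0.0319 and 0.0382) and Hmox1 without WT DMSO 1, 2 or 3 (0.0197, 0.0402 and 0.0406). Of 30 NRF2 target genes, 10 were lower and 0 higher in KO untreated vs WT DMSO (17 down, adjusted over the list alone; camera adjusted p = 8.25e-19, adjusted p = 0.103 with an estimated correlation). Without the 4 intron-rich libraries 5 were lower. Gstm1 went from 664.9 to 123.1 CPM, the aldehyde oxidase Aox1 from 213.6 to 43.4 CPM and Ugdh from 168.4 to 68.3 CPM (edgeR adjusted p = 0.000471, 0.000488 and 0.00053). Of 24 glutathione genes, 5 were lower (8 down, adjusted over the list alone; camera adjusted p = 2.94e-10, adjusted p = 0.361 with an estimated correlation). Ces1b, a carboxylesterase of a cluster of similar genes, went from 68.9 ± 11.1 to 6.95 ± 3.13 CPM, and Fitm1, a lipid droplet gene, from 10.9 ± 2.35 to 1.05 ± 0.47 CPM (edgeR adjusted p = 3.77e-05 and 0.00455). Malic enzyme Me1, Cyp2a5, Ugt2b35, Blvrb and Ftl1 fell by 1.43, 2.55, 1.76, 0.88 and 0.92 on the log2 scale in this contrast (edgeR adjusted p = 0.00903, 0.0317, 0.00286, 0.0375 and 0.0465).

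Of 27 acute phase genes, 6 were lower and 0 higher in KO untreated (9 down, adjusted over the list alone; camera adjusted p = 2.36e-09, adjusted p = 0.491 with an estimated correlation). The mean acute phase score of the list did not differ detectably, at −0.938 for KO untreated minus WT DMSO (exact permutation p = 0.1143), or −0.4318 without WT DMSO 4 (exact permutation p = 0.2571). Metallothioneins Mt1 and Mt2 went from 594.3 to 81.1 and from 561.0 to 44.1 CPM (edgeR adjusted p = 0.00499 and 0.00943). Saa4 and Orm3, members of families with near-identical copies, fell by 1.57 and 3.14 on the log2 scale (edgeR adjusted p = 0.00403 and 0.0142). Of 29 immediate early genes, 6 were lower (17 down and 1 up, adjusted over the list alone; camera adjusted p = 5.39e-12, adjusted p = 0.103 with an estimated correlation). Among them were Junb 4.46-fold, Gadd45a 7.29-fold, Fosl2 3.24-fold and Stat3 2.15-fold. Those counts of 6 and 6 were 4 and 2 without WT DMSO 4, and 3 and 0 without the 4 intron-rich libraries. The acute phase score of WT DMSO 4 was 1.46, against −0.741 to −0.301 in the other WT DMSO libraries. The chemokine Cxcl1 was 12.4-fold lower and the iron hormone Hamp 3.87-fold lower (edgeR adjusted p = 0.00449 and 0.0466). Among the largest rises in KO untreated were the glutamate receptor gene Gria3 (6.45-fold), the lectin gene Clec2h (5.63-fold), Ptgds, a prostaglandin D2 synthase (4.04-fold), Adamts7 (3.98-fold), Zfp618 (3.75-fold) and Asb2 (3.70-fold), with edgeR adjusted p from 0.00499 to 0.0491. The macrophage marker Adgre1 was 2.19-fold higher, 1 of 16 Kupffer cell and macrophage markers (camera adjusted p = 0.000471, adjusted p = 0.598 with an estimated correlation). Syt12 and the citrate transporter Slc13a5 were lower (edgeR adjusted p = 0.0239 and 0.0152), with Syt12 at 39.0 CPM in WT DMSO 4 and 1.87 to 4.93 CPM in the other WT DMSO libraries.

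KO untreated vs WT DMSO called 223 genes, 66 higher and 157 lower, and the balance reversed with limma on log2 FPKM, with 167 higher and 87 lower (pseudocount 1) or 147 and 88 (pseudocount 0.1). Same-numbered libraries of these groups deviated together (r = 0.371 to 0.483 over 4 pairs). In none of the 4 pairs was each library the other's best match, and libraries 1 and 2 of both groups are the intron-rich ones, so the numbers are not shown to be pairs. The replicate number was still tried as a block. In a fit of only these 2 groups 20 genes were called without the block and 73 with it, 56 of them among the 223, and in the fit of all groups the 223 became 250. The count was 104, 131 and 108 without KO untreated 2, 3 and 4, and of 33 named genes 21 stayed called without each library in turn. Ptgds, Asb2, Syt12, Slc13a5, Cyp2a5, Junb, Gadd45a, Fosl2, Stat3, Blvrb, Ftl1 and Hamp did not, with highest adjusted p of 0.0509 (Asb2, without KO untreated 4) to 0.167 (Ptgds, without KO untreated 2). All KO libraries lay on the low side of the ribosomal RNA split with 1 WT DMSO library, so a comparison within that set rests on WT DMSO 4. Without WT DMSO 4 and WT CDDO-Me 1, 185 genes were called. With the split as a term 698 genes were called, 160 higher and 538 lower, 164 of them among the 223.

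Of the 90 genes that rose with the drug in WT, 28 were among the 157 lower in KO untreated, where independent lists would share 0.872. They included Nqo1, Gstm1, Gstm3, Gsta1, Gsta2, Ugdh, Ugt2b35, Aox1, Blvrb and Ftl1. Of the 28 that fell, 0 were among the 66 higher, where 0.114 would be shared, and 3 genes changed in the same direction in both contrasts. Both contrasts use the WT DMSO libraries, which pushes their fold changes the same way and so works against the 28. Across genes the fold changes of the 2 contrasts correlated at r = 0.253, against a mean of 0.512 in 20 simulations without effects. The covariance was 0.0887 against 0.0760, a difference of 0.0126. The simulated libraries are independent, whereas WT DMSO 1 and 2 and KO untreated 1 and 2 stood apart together. Nothing is therefore read from that difference. With the WT DMSO libraries divided between the contrasts, the 6 ways of doing so gave r from −0.431 to −0.0127 and 12 to 132 shared genes. The 132, with the drug set against WT DMSO 1 and 2, were 96 up and 36 down with the drug, where independent lists would share 44.6 and 17.4. This way sets both intron-rich WT DMSO libraries against WT CDDO-Me, and KO untreated against the WT DMSO libraries that are not intron-rich. Its excess, and its r of −0.431, therefore cannot be told from the intron-rich state. The other 5 ways shared 12 to 18, where such lists would share fewer than 1. The 28 became 17 without KO untreated 2.

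Under the drug both groups were injected alike. KO CDDO-Me vs WT CDDO-Me called 534 genes, 172 higher and 362 lower in KO. The balance was 687 and 315 with limma on log2(FPKM + 1), 974 and 1071 in an edgeR fit of only these 2 groups, and 725 and 757 without the 4 intron-rich libraries. Nqo1, Gclc, Srxn1 and Txnrd1 had log2 fold changes of −4.89 ± 0.32, −2.52 ± 0.20, −2.85 ± 0.27 and −1.44 ± 0.23 (edgeR adjusted p = 1.06e-07, 7.81e-07, 5.22e-06 and 0.00134). Gclm and Hmox1 were not called, at −0.55 ± 0.27 and −2.14 ± 0.66 (edgeR adjusted p = 0.326 and 0.0902), though Hmox1 was without WT DMSO 4 (adjusted p = 0.00321). Of 30 NRF2 target genes, 23 were lower and 0 higher in KO, and all 30 fold changes were negative (27 down, adjusted over the list alone; camera adjusted p = 2.84e-47, adjusted p = 0.00634 with an estimated correlation). Gsta1 was 66.5 ± 24.3 CPM in WT CDDO-Me and 0.303 ± 0.065 in KO CDDO-Me, and Gstm1 4842 ± 552 and 115.3 ± 4.62 (edgeR adjusted p = 4.43e-08 for both). Gstm3 was 405.8 ± 69.9 and 4.96 ± 1.26 (edgeR adjusted p = 1.58e-07). Of 24 glutathione genes 13 were lower (17 down, adjusted over the list alone; camera adjusted p = 5.78e-24, adjusted p = 0.111 with an estimated correlation).

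Of 22 glucuronidation and sulfation genes 7 were lower and 1 higher in KO CDDO-Me vs WT CDDO-Me (camera adjusted p = 8.35e-06, adjusted p = 0.269 with an estimated correlation), with Ugt2b35 9.83-fold lower. Of 23 cytochrome P450 genes 5 were lower (camera adjusted p = 4.92e-09, adjusted p = 0.18 with an estimated correlation). Cyp2a5 read 3084 CPM in WT CDDO-Me and 35.99 in KO CDDO-Me, and Cyp1a2 and Cyp2d22 fell by 2.12 and 0.62 on the log2 scale (edgeR adjusted p = 1.66e-05, 0.00303 and 0.00559). Of 25 bile acid genes 6 were lower (camera adjusted p = 0.000623, adjusted p = 0.132 with an estimated correlation). Among them were Abcc3, 708.1 ± 53.7 against 40.4 ± 8.90 CPM, and Abcc4 (edgeR adjusted p = 4.43e-08 and 2.8e-06). Of 13 pentose phosphate and NADPH genes 5 were lower, including Tkt, Pgd and Me1 (camera adjusted p = 7.58e-05, adjusted p = 0.259 with an estimated correlation). Of 24 heme and iron genes 5 were lower, including Blvrb 6.22-fold and both ferritin chains, Ftl1 2.91-fold and Fth1 2.47-fold (camera adjusted p = 0.000374, adjusted p = 0.259 with an estimated correlation).

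Of 22 fatty acid and triglyceride synthesis genes 6 were higher and 1, Me1, lower in KO CDDO-Me (camera adjusted p = 1.63e-07, adjusted p = 0.132 with an estimated correlation). The lipogenic transcription factor Srebf1 read 363.1 ± 68.2 CPM against 93.3 ± 8.33, Acly 591.2 ± 74.2 against 222.4 ± 19.6 and Elovl5 443.9 ± 117.5 against 198.8 ± 27.4 (edgeR adjusted p = 0.00272, 0.00561 and 0.0166). Of 25 urea cycle and amino acid catabolism genes 6 were higher (camera adjusted p = 5.37e-07, adjusted p = 0.26 with an estimated correlation), among them Got1, Tat, Hal and Gls2, 2.07- to 2.95-fold. Of 15 pericentral hepatocyte genes Cyp1a2, Aldh1a1 and Tbx3 were lower (camera adjusted p = 1.3e-05, adjusted p = 0.259 with an estimated correlation). Of 15 periportal genes Hal, Gls2, Ass1 and Sds were higher (camera adjusted p = 0.000589, adjusted p = 0.29 with an estimated correlation). With the ribosomal RNA split as a term, the pericentral count went from 3 to 1, the periportal from 4 to 0, the urea from 6 to 2 and the lipid synthesis from 6 to 3. The serine and ATF4 genes Psat1, Trib3 and Atf5 were lower, 3 of 25 unfolded protein and ATF4 genes (camera adjusted p = 0.0454, adjusted p = 0.7 with an estimated correlation). Fgf21 was 34.3-fold lower (edgeR adjusted p = 0.000505), 1 of 3 genes called among 30 fatty acid oxidation and PPAR alpha genes. All 30 had negative fold changes (14 down, adjusted over the list alone; camera adjusted p = 1.99e-10, adjusted p = 0.259 with an estimated correlation).

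Single genes higher in KO CDDO-Me than in WT CDDO-Me included Chrna4 (14.3-fold), Ptgds (11.2-fold), the proton pump gene Atp4a (11.1-fold), Cyp17a1 of steroid synthesis (8.59-fold), the fatty acid binding protein gene Fabp5 (7.14-fold) and the immunoglobulin heavy chain gene Ighm (5.68-fold), with edgeR adjusted p from 8.11e-05 to 0.0303. Ighm was the called gene among 7 lymphocyte markers (camera adjusted p = 0.00532, adjusted p = 0.132 with an estimated correlation). The count of 534 in this contrast was 334, 283 and 280 without WT CDDO-Me 2, 3 and 4, 303, 265 and 295 without KO CDDO-Me 1, 2 and 3, and 820 without WT DMSO 4. Of 46 genes, a part of those named for this contrast, 34 stayed called without each library in turn. Nfe2l2, Chrna4, Cyp17a1, Elovl5, Hal, Gls2, Trib3, Atf5, Aldh1a1, Tbx3, Ass1 and Sds did not, with highest adjusted p of 0.0502 (Aldh1a1, without KO CDDO-Me 2) to 0.156 (Sds, without KO CDDO-Me 2). On the KO side of the ribosomal RNA split a comparison rests on WT CDDO-Me 1. With the split as a term 357 genes were called, 229 of them among the 534, and 21 NRF2 target genes were lower.

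**Figure D4:**
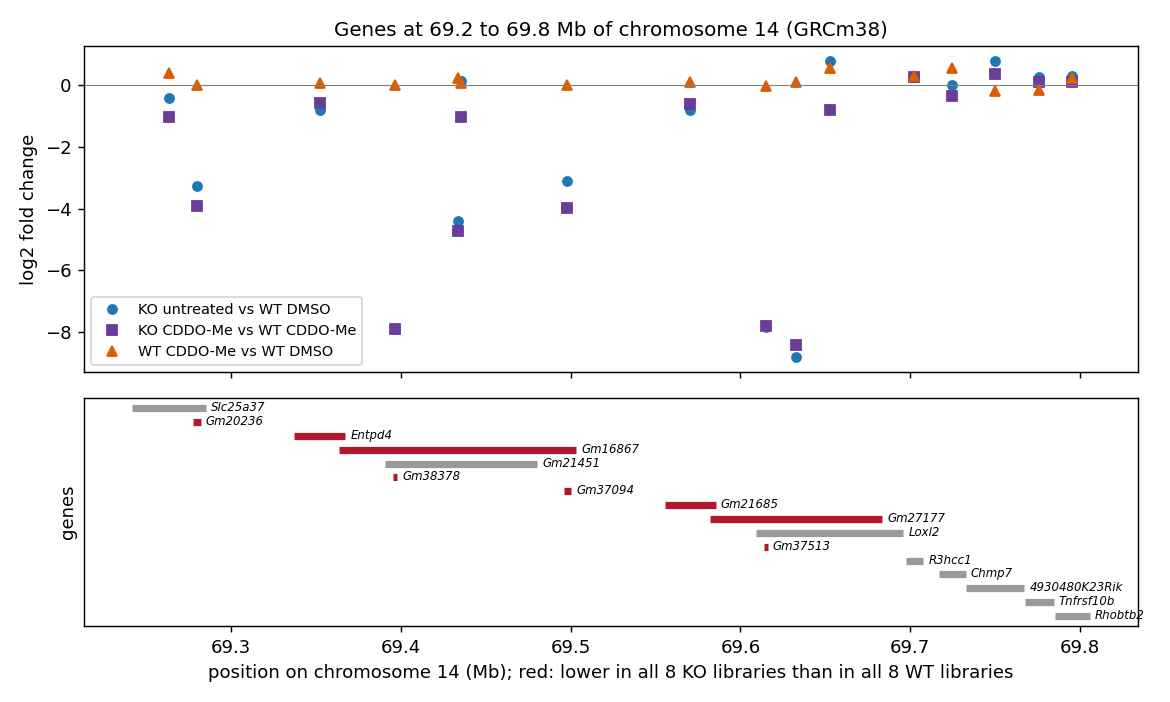
Log2 fold changes (y axis) of tested genes around positions 69277601 to 69683286 of chromosome 14 in 3 contrasts, above a map of the genes (GRCm38, Mb on the x axis). Red genes were lower in all 8 KO libraries than in all 8 WT libraries. Gm27177 read −8.83 in KO untreated vs WT DMSO and 0.11 in WT CDDO-Me vs WT DMSO.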

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

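The tests of vehicle, library depth, ribosomal RNA, Malat1, chromosome 14, chromosome 2 and the other splits of the libraries were chosen only after the results were seen. Those of unspliced RNA and of genomic DNA in the 4 intron-rich libraries were written before.

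The first pattern is the set of 21 genes called in KO CDDO-Me vs KO untreated, where, by the labels, only the treated mice were injected. Both WT groups were injected, so vehicle alone would leave these genes level between them, yet their mean signed log2 difference, WT CDDO-Me minus WT DMSO, was 0.5734, with 17 of 21 in the KO direction (exact 2-sided permutation p = 0.02857, the smallest possible). It was 0.4075 without WT DMSO 1 and 2 (exact permutation p = 0.06667, the smallest possible). With all WT libraries, the set thus moved with the drug in WT. WT mice have NRF2, so this cannot show what moved these genes in KO, and injection and vehicle are not excluded there. Over all genes the 2 drug contrasts correlated at r = 0.399, and at −0.0397 without the 4 intron-rich libraries. The WT difference is itself not settled, because WT DMSO 1 and 2 are intron-rich like KO untreated 1 and 2. Without them the permutation test could not reach a p under 0.05. The KO difference of 2.19 belongs to genes picked by that same contrast, so it cannot divide the set between drug and vehicle. For the acute phase genes the same WT difference was 0.4889 (exact permutation p = 0.4571), or 0.9951 without WT DMSO 4 (p = 0.02857, the smallest possible), so for them drug and vehicle cannot be told apart. A drug effect that needs no Nrf2 may account for part of the set and stays a hypothesis, as KO mice given vehicle were not part of these groups.

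The second pattern is the 4 libraries, WT DMSO 1 and 2 and KO untreated 1 and 2, with 0.673 to 0.967% of counts in genes annotated as sense-intronic or TEC (unsettled loci), against 0.186 to 0.407% in the other 12. Depth does not account for it, since the 3 other libraries of no larger total reached 0.3032%, nor does residual ribosomal RNA, of which the 4 held as little as 0.5534% where another library held 12.6%. Genomic DNA could be a source: receptor genes of smell and pheromone sensing, which liver is not known to express, took at least 342.6 CPM in the 4 and at most 197.0 in the others. Malat1, a nuclear RNA named after its values were seen, was 10910 CPM higher on average in the 4, where genomic DNA would add 0.621, which argues against it for that part. Unspliced or nuclear RNA cannot be told from the rest, because long-intron genes exceeded short-intron genes by 0.01419 on the log2 scale in WT DMSO and 0.16 in KO untreated, and no biological explanation was tested.

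The third pattern is a segment of chromosome 14 (69277601 to 69683286), whose genes were named after their values were seen. In it 8 of 12 tested genes within 500 kb were lower in all KO than in all WT libraries, among 127 such genes in the genome, where chance gives 0.00777% or 1.26 genes. Gm27177 had 68 to 1125 counts per WT library and 0 or 1 per KO library, and Entpd4, near a similar gene, had a log2 fold change of −0.78. No window held more than 5 such genes in 10000 permutations of position (permutation p = 1e-04, the smallest they can give). The permutation placed each gene on its own, but some of the 8 form pairs with near-equal changes. In KO untreated vs WT DMSO, Gm20236 and Gm37094 had log2 fold changes of −3.27 and −3.12, and Entpd4 and Gm21685 −0.78 and −0.81. Gm38378 and Gm37513 had −7.90 and −7.83. Reads may be shared within such pairs, so the 8 may not be independent and the permutation p may overstate the crowding. A segment that differs between the mouse lines remains possible. Gm38378 and Gm37513 had 0 counts in every KO library, with the drug or without, and 5 to 222 and 7 to 209 per WT library. With the drug in WT, 0 of the 8 genes were called (log2 fold changes −0.01426 to 0.247), which gives no sign of control by NRF2. Loss of Nrf2 activity still cannot be excluded, because other genes lower in every KO library also failed to rise with the drug. The segment's median drug response in WT was 0.04465 and that of the other 119 genes 0.239, with a lower quartile of −0.03. Genes within 20 Mb of Nfe2l2 on chromosome 2 were called at a rate close to that of others in KO untreated vs WT DMSO. It was 3 of 204 (1.47%) against 220 of 16002 (1.37%), with no detectable excess (1-sided Fisher's exact p = 0.535). That gives no sign of a passenger segment there that alters many genes, and with 3 calls a segment that alters few could be missed.

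Other splits of the same libraries tested whether chance can be excluded. For WT CDDO-Me vs WT DMSO 1 of 35 splits, the real one, gave 118 calls, and the highest other gave 1, so chance is excluded at 0.05. The same held for KO CDDO-Me vs WT CDDO-Me (1 of 35, 534 calls, highest other 0 by edgeR). A rank of 1 of 35 is the lowest these splits can give, and it cannot separate treatment or genotype from technical differences. WT DMSO 1 and 2 were intron-rich and no WT CDDO-Me library was. WT CDDO-Me 2 to 4 lay across the ribosomal RNA split from all KO CDDO-Me libraries. For KO CDDO-Me vs KO untreated the real split also gave the most calls (1 of 35, 21 calls), but another gave 16. That split set KO untreated 1 and 2 with KO CDDO-Me 3 and 4 against the rest. The 21 became 4 without the 4 intron-rich libraries and 0 with the replicate block in only the groups compared. The rank passes 0.05, but these splits cannot separate treatment from the structure of the samples. For KO untreated vs WT DMSO 2 of 35 splits gave as many as 223, so chance is not excluded. The other, with 7586 calls, set the 4 intron-rich libraries against the rest and points to a structure of the samples, and among the 8 splits that part all same-numbered pairs the highest other gave 1. In fits of only these 2 groups the count was 20, and 73 with the replicate number as a block, which in the fit of all groups gave 250. For the interaction 5 of 100 splits gave as many as 21, the real one among them. Of the other 4, 3 (205, 73 and 22 calls) kept the WT groups as labelled and so still held the WT drug response. The highest, with 603, set the intron-rich WT libraries and the intron-rich KO libraries on opposite sides. These splits therefore cannot decide whether chance is excluded for the interaction.

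In groups of 4, a library was listed when its gap to the nearest other exceeded 0.829 of the group's range. Of 504 groups, 30 had such a library, where chance gives 25.2. Among genes, 22 of 344 did, where chance gives 17.2. By library, WT CDDO-Me 4 had 5 and KO CDDO-Me 3 and KO untreated 4 had 4 each. Of 16 groups of library measures 3 did, where chance gives 0.8: the total of WT CDDO-Me 1 (gap 0.987 of the range, 99284626 counts), and in WT CDDO-Me 4 the protein-coding share (0.875, 77.8% against 90.9 to 92.8%) and the mitochondrial ribosomal RNA share (0.932, 12.4% against 0.752 to 1.54%). Of 144 groups of list scores 5 did, where chance gives 7.2. These were the interferon score of WT DMSO 4 (0.964), the cell cycle scores of WT DMSO 2 (0.873) and WT CDDO-Me 2 (0.844), the inflammatory score of KO untreated 4 (0.86) and the pentose phosphate score of KO CDDO-Me 3 (0.861).

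The gaps for genes in WT DMSO were 0.95 for Fgf21 (library 4, 0.0918 CPM against 1.00 to 1.11), 0.965 for Gsta2 (library 3) and 0.862 for Gls2 (library 3). In WT CDDO-Me they were 0.845 for Gclm and 0.937 for Atf3 (library 1), 0.844 for Ass1 (library 2), 0.943 for Itih3 (library 3), and 0.901 for Hmox1, 0.854 for Mt2 and 0.892 for Fosl2 (library 4). Hmox1 there read 266.0 CPM against 94.96 to 105.2. In KO untreated they were 0.859 for Ugdh (library 1), 0.944 for Thrsp (library 2, 954.6 CPM against 299.1 to 319.1), 0.867 for Cyp1a2 (library 3), and 0.943 for Cyp17a1, 0.857 for Gls2 and 0.948 for Trib3 (library 4). In KO CDDO-Me they were 0.974 for Aox1 (library 1), 0.832 for Pgd, 0.857 for Syt12 and 0.976 for Slc13a5 (library 3), and 0.849 for Cyp2a4 and 0.911 for Ptgds (library 4).

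The drug response differed between WT and KO, by the interaction test of edgeR, for 12 named genes. The log2 differences were 2.583 for Nqo1, 2.067 for Gclc, 2.147 for Srxn1, 6.999 for Cbr3, 6.91 for Cyp2a4, 5.405 for Gsta1, 4.164 for Gstm3, 3.366 for Gsta2, 2.959 for Gstm1, 2.143 for Abcc4, 1.755 for Blvrb and 2.862 for Marco. By camera with the preset correlation it differed for 22 lists, none of which were called with an estimated one (adjusted p = 0.0585 to 0.72 with an estimated correlation). Their median log2 differences were 1.115 for NRF2 targets, 0.7225 for glutathione, 0.2482 for pentose phosphate, 0.3618 for cytochrome P450, 0.9077 for glucuronidation, 0.3345 for bile acid, −0.5362 for fatty acid synthesis and 0.3348 for cholesterol synthesis genes. They were 0.5348 for fatty acid oxidation and PPAR alpha, −0.3374 for urea cycle, −0.8233 for immediate early, −1.394 for acute phase, −0.8421 for inflammatory, 0.1296 for heme and iron and 0.5069 for female-biased genes, and 0.3876 for mitochondrially encoded ones. For cell markers they were −0.104 for hepatocyte, 0.6857 for pericentral, −0.4696 for periportal, 0.4494 for Kupffer cell, 1.007 for stellate cell and 0.6884 for endothelial lists.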

How the results depend on the processing

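The alternatives that left out the 4 intron-rich libraries, took the intronic share as a covariate, thinned WT CDDO-Me 1, blocked by replicate number in a fit of only the groups compared, or took the ribosomal RNA split as a term were chosen after the data were seen, while the others were planned. For a part of the genes the naming rule selected, 2533 results under the alternatives kept direction and side of the threshold, 369 kept the direction and lost the call, 45 gained a call and 18 changed direction. Without single libraries the numbers were 2197, 315, 9 and 7. The model with sex as a covariate was not run. Thinning WT CDDO-Me 1 gave 109, 22, 224, 527 and 21 calls in the 5 contrasts. The cause was not tested for any change below, except that fits of only the groups compared and fits without libraries hold fewer samples.

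For WT CDDO-Me vs WT DMSO, 118 calls became 471 with DESeq2 (259 up, 212 down), 5027 with limma-voom and quality weights, 72 with only the groups compared, 226 with the replicate block in all groups, 56 with the block in only the groups compared, and 40 against a minimum fold of 1.5. The weights ran from 0.156 (WT DMSO 4) to 3.11 (KO CDDO-Me 2). Single libraries gave 54 (without WT CDDO-Me 2) to 219 (without WT DMSO 4).

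For KO CDDO-Me vs KO untreated, 21 calls became 298 with DESeq2, 1823 with limma-voom, 51 with no filter, 46 with the block in all groups, 88 without libraries 25 and 27, 63 with limma on log2(FPKM + 1), 60 with FPKM + 0.1, 5 against a fold of 1.5, 4 without the 4 intron-rich libraries and 73 with the intronic covariate. With the block in only the groups compared edgeR called 0, where the fit of all groups had 2564 genes at an unadjusted p under 0.05 and DESeq2 called 298. Single libraries gave 4 (without KO untreated 2) to 133 (without WT DMSO 4).

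For KO untreated vs WT DMSO, 223 calls became 657 with DESeq2, 20 with only the groups compared, 122 with log2(FPKM + 1) and no filter, 50 against a fold of 1.5, 86 without the 4 intron-rich libraries, 748 with the intronic covariate, 698 with the ribosomal RNA term and 73 with the block in only the groups compared. Single libraries gave 104 (without KO untreated 2) to 271 (without WT DMSO 1).

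For KO CDDO-Me vs WT CDDO-Me, 534 calls became 1125 with DESeq2, 3096 with limma-voom, 2045 with only the groups compared, 811 with the block in all groups, 1826 with the block in only the groups compared, 1002 with FPKM + 1, 999 with FPKM + 0.1, 135 against a fold of 1.5, 1482 without the 4 intron-rich libraries and 2078 with the intronic covariate. Single libraries gave 265 (without KO CDDO-Me 2) to 820 (without WT DMSO 4).

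For the interaction, 21 calls became 39 with upper-quartile scaling, 176 with DESeq2, 161 with limma-voom, 38 with no filter, 33 with the filter of 1 CPM in 8 libraries, 42 with the block in all groups, 50 and 48 with FPKM + 1 and FPKM + 0.1, 42 with FPKM + 1 and no filter, 13 against a fold of 1.5, 67 without the 4 intron-rich libraries and 154 with the intronic covariate. Single libraries gave 18 (without KO untreated 3) to 48 (without KO untreated 1).

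List calls with an estimated correlation numbered 1, 0, 0, 1 and 0, against 20, 16, 14, 21 and 22 with the preset one. Without single libraries they were 17 to 23, 12 to 20, 11 to 17, 18 to 22 and 18 to 23. Genes shared by the WT and KO drug responses numbered 2, with DESeq2 16 and at an adjusted p under 0.01 by edgeR 0, and without single libraries 0 to 9. Genes shared by the WT drug response and the baseline genotype difference numbered 28, with DESeq2 52, at an adjusted p under 0.01 11, and without single libraries 17 to 26. The correlation of the WT and KO drug responses over genes, 0.399, was 0.565 with limma-voom, 0.11 with no filter, 0.559 without libraries 25 and 27, −0.0397 without the 4 intron-rich libraries and 0.134 with the intronic covariate. Without single libraries it ran from 0.242 (WT DMSO 2) to 0.532 (WT DMSO 4). It was computed in these fits after the result was seen.

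Directions changed for 5 results of 4 genes, none of them called. For Hmox1, WT CDDO-Me vs WT DMSO, the log2 fold change was −0.30 without the 4 intron-rich libraries. For Gclc, KO CDDO-Me vs KO untreated, it was −0.1455 with FPKM + 1 with or without the filter, −0.1478 with FPKM + 0.1, −0.02106 without the 4 intron-rich libraries and −0.003985 with the covariate. Without single libraries it ran from −0.07634 (KO CDDO-Me 3) to 0.1748 (KO CDDO-Me 1), and was −0.04266 without KO untreated 2. For Gclm, KO untreated vs WT DMSO, it was 0.2262 with limma-voom, 0.01068 without libraries 25 and 27, 0.09457 with FPKM + 1 with or without the filter, and 0.0991 with FPKM + 0.1. Without single libraries it ran from −0.2992 (WT DMSO 2) to 0.1157 (WT DMSO 3), and was 0.01138 without WT DMSO 4 and 0.05461 without KO untreated 1. For Nfe2l2, genotype by treatment interaction, it was −0.6298 without the 4 intron-rich libraries and −0.1417 (without KO untreated 1) to 0.3511 (without KO untreated 3) without single ones. For Hmox1, genotype by treatment interaction, it was 1.104 with limma-voom, 1.017 without libraries 25 and 27, 0.1075 with FPKM + 1 with or without the filter, 0.07436 with FPKM + 0.1 and 0.2241 with the ribosomal RNA term. Without single libraries it ran from −1.186 (WT CDDO-Me 4) to 0.8632 (WT DMSO 4).

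Some scalings moved the median log2 fold change of all genes. It was −0.1055 in KO CDDO-Me vs KO untreated with upper-quartile scaling. On the FPKM scale it was −0.1494 and −0.1918 (pseudocount 1 and 0.1) in that contrast, 0.1267 and 0.1694 in KO untreated vs WT DMSO, and with pseudocount 0.1 −0.122 in WT CDDO-Me vs WT DMSO and 0.1208 in KO CDDO-Me vs WT CDDO-Me. The share of calls upward moved with it in some of these fits. With FPKM + 1, it was 167 up and 87 down in KO untreated vs WT DMSO and 687 up and 315 down in KO CDDO-Me vs WT CDDO-Me, where counts gave 66 and 157, and 172 and 362. In KO CDDO-Me vs KO untreated it was 54.0% upward with FPKM + 1, against 81.0% with counts. It moved the other way there with upper-quartile scaling (84.6%), and in WT CDDO-Me vs WT DMSO with FPKM + 0.1 (80.4%, against 76.3% with counts).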

Other observations

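The lists and their tests were fixed in advance, while the list tests without WT DMSO 4 alone and the values of the 4 intron-rich libraries, Malat1 and Neat1 were chosen only after the result was seen. In KO CDDO-Me vs WT CDDO-Me, markers of endothelial and stellate cells passed downward. All 16 endothelial markers and 15 of 16 stellate cell and fibroblast markers had negative fold changes, with Stab1 and Pdgfra called (camera adjusted p = 0.000113 and 0.000151, adjusted p = 0.272 and 0.34 with an estimated correlation). All 8 neutrophil and monocyte markers were negative and 0 were called by edgeR (camera adjusted p = 0.0179, adjusted p = 0.435 with an estimated correlation). Of 15 mitochondrially encoded genes, mt-Atp8 and mt-Nd4l were lower and 13 were negative (camera adjusted p = 8.05e-06, adjusted p = 0.272 with an estimated correlation). In WT CDDO-Me 4 mitochondrial ribosomal RNA took 12.4% of counts. Of 2 adipocyte, mesothelial and pancreatic markers tested, the pancreatic protease gene Cela1 was higher (camera adjusted p = 0.0179, adjusted p = 0.132 with an estimated correlation). Immediate early and cell cycle genes passed downward with 1 and 0 called (camera adjusted p = 0.0449 and 0.0378, adjusted p = 0.551 and 0.522 with an estimated correlation). In the fit blocked by replicate number neither passed (camera adjusted p = 0.0572 and 0.0558 in KO CDDO-Me vs WT CDDO-Me).

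In KO untreated vs WT DMSO, 23 of 24 cholesterol synthesis genes had positive fold changes with 0 called by edgeR (camera adjusted p = 1.72e-05, adjusted p = 0.598 with an estimated correlation). Glucuronidation and cytochrome P450 genes passed downward with 4 and 2 called (camera adjusted p = 0.00272 and 0.00188, adjusted p = 0.621 and 0.606 with an estimated correlation). Of 24 heme and iron genes 3 were lower and the list missed the threshold (camera adjusted p = 0.0764). Fatty acid synthesis, lymphocyte, endothelial and adipocyte, mesothelial and pancreatic lists passed upward (camera adjusted p = 0.0174, 0.0174, 0.00173 and 0.0168, adjusted p = 0.598, 0.293, 0.598 and 0.183 with an estimated correlation). The mitochondrially encoded and nuclear-retained lists passed downward (camera adjusted p = 0.0226 for both, adjusted p = 0.783 and 0.361 with an estimated correlation). Mitochondrial ribosomal RNA took 5.28, 5.32 and 7.25% of counts in WT DMSO 1 to 3, 0.772% in WT DMSO 4 and 0.527 to 0.873% in KO untreated. The mitochondrial list includes the ribosomal RNA genes mt-Rnr1 and mt-Rnr2, so that difference enters it directly. How much of the list's fall it makes up was not tested. The interferon list had a median log2 fold change of −0.58 and a camera direction upward (adjusted p = 0.977), and without WT DMSO 4 a median of 0.95 with 5 genes called upward (camera adjusted p = 1.64e-14, adjusted p = 0.155 with an estimated correlation).

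In KO CDDO-Me vs KO untreated, heme and iron, hepatocyte, Kupffer cell, heat shock and erythroid lists passed camera upward (adjusted p = 0.0129, 0.0114, 0.00681, 0.03 and 0.0417) and fatty acid synthesis, interferon and pericentral lists downward (0.0129, 0.0114 and 0.0417). By edgeR 0 of their genes were called, and the lowest adjusted p with an estimated correlation was 0.767. Lists that passed in no drug contrast of WT or KO were circadian clock (camera adjusted p = 0.756 in WT), lymphocyte (0.543), inflammatory (0.492), cholangiocyte (0.736), male-biased (0.557), female-biased (0.709), nuclear-retained (0.557), periportal (0.058), neutrophil and monocyte (0.068), mitochondrially encoded (0.244), and adipocyte, mesothelial and pancreatic (0.691). Cytochrome P450, hepatocyte, erythroid, cell cycle and immediate early lists did not pass in WT (camera adjusted p = 0.449, 0.691, 0.407, 0.118 and 0.146). Of their genes in WT CDDO-Me vs WT DMSO edgeR called Cyp2a4 and Cyp2a5 (cytochrome P450), Gstp1 (male-biased), Cyp2a4 (female-biased) and Sds (periportal). The median of the male-biased, female-biased and neutrophil lists (−0.05, −0.14 and −0.02) differed in sign from their camera direction there, as did those of the cholangiocyte, fatty acid oxidation, glucose, bile acid and pericentral lists (−0.32, 0.02, 0.04, 0.03 and 0.08) in KO untreated vs WT DMSO. So did those of the male-biased, cholangiocyte and neutrophil lists in the interaction, of the male-biased and lymphocyte lists in KO CDDO-Me vs KO untreated, and of the erythroid list in KO untreated vs WT DMSO. None of these lists passed in the contrast named.

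On the first principal component the 4 intron-rich libraries lay at −32.6, −41.4, −54.7 and −43.4 and the other 12 between 0.26 and 35.3. Malat1 read 12270 to 18410 CPM of all counts in the 4 and 2453 to 6613 in the others, and Neat1 13230 to 26250 and up to 9555.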
